A study of Mus musculus with 12 samples.

How the data were processed

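RNA from 3T3-L1 cells, a mouse preadipocyte line that can be turned into fat cells in culture, was measured on 12 Clariom S mouse arrays, 2 for each of 6 groups: a control without compound, squalene (SQ) and 4 ethylene glycol derivatives of squalene (mono-, di-, tri- and tetra-SQ). The compounds were given at 5 µM for 14 days, per the labels. RNA was extracted with ISOGEN and labelled with a whole-transcript kit, per the labels. The authors normalized the array signals with SST-RMA in the Transcriptome Analysis Console 4.0.1, per the series' design text, and the deposited values are log2 signals with 2 decimals, per the file headers. The authors also deposited, for each compound against control, a signed fold change and p-values with their false discovery rate, per the file headers; the test behind them is not stated there. A further deposited table holds log2 values of the same arrays together with control and spike-in probe sets. Its values differ from those of the main table by a median of 0.08 to 0.082 per array (across-gene correlation at least 0.9996).

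All comparisons start from the deposited log2 signals of 22206 probe sets, without further scaling or filter. Of these, 21367 carried 1 gene symbol, 836 several and 3 none, per the file headers' annotation columns. Of 21154 distinct single symbols, 19689 were found in the RefSeq table of the mouse assembly GRCm38 (mm10), which gave the coordinates. Genes were named only from probe sets with 1 symbol. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes, two-sided moderated tests) over all 12 arrays and 6 groups, which leaves 6 residual degrees of freedom. The p values were adjusted over all probe sets with the Benjamini-Hochberg method, and the threshold was 0.05. The comparisons were each compound against control, each derivative against SQ, neighbouring derivatives, a linear trend over mono-, di-, tri- and tetra-SQ, which reads the prefixes as numbers of glycol units, and an F test over the 5 compounds.

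Gene lists were tested with limma's camera at its preset correlation of 0.01, against all other genes, on 1 averaged value per symbol. The tests formed a family of 145 for the comparisons with control and one of 116 for those with SQ. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were run beside it. The 29 lists cover lipogenesis, mature adipocyte genes, adipogenic transcription factors, preadipocyte and anti-adipogenic genes, lipolysis, cholesterol synthesis, LXR targets, fatty acid oxidation, oxidative phosphorylation, brown and beige adipocyte genes, inflammatory mediators, the NF-kB and Toll-like receptor pathway, interferon-stimulated genes, complement and acute phase, extracellular matrix, matrix remodelling enzymes, TGF-beta and myofibroblast genes, cell cycle, oxidative stress defence, the unfolded protein and integrated stress response, insulin signalling and glucose uptake, glycolysis, glucocorticoid targets, cytosolic ribosomal proteins, and markers of macrophages, osteoblasts, chondrocytes, muscle and endothelium. They hold 599 entries with 575 distinct symbols. Of these, 16 symbols (18 entries) could not be used because the array pairs them with a second gene, among them Srebf1, Scd2, Gata3 and Pdgfra. In 22 of the 145 list tests against control and 23 of the 116 against SQ, the list's median, its mean and the direction of the test differed in sign; 0 of them passed the threshold. Intervals (95%) for a list come from limma on the mean of its members per array.

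The groups, fits, lists and thresholds, and the rule for naming genes, were chosen before the data were examined. By that rule, genes past the test with 1 symbol that is not a predicted locus are named first (in each comparison with control, the 8 highest and 8 lowest that separate the arrays). Their level had to reach the median of all probe sets in the higher group. Where a comparison calls no gene, the 3 with the smallest p by the same filter are named as not past the test. Up to 3 members with the largest log2 difference are named from each list that passed or had at least 3 members past the gene test, and always from lipogenesis, mature adipocyte, cholesterol synthesis and inflammatory mediators. The fits and the list test were tested on simulated data. At the residual spread of the 12 arrays, with 22206 genes and 50 changed at each fold in SQ against control, the fit recovered 0% of 1.5-fold, 4% of 2-fold, 54% of 4-fold and 84% of 8-fold changes, with 2 unchanged genes called. At the spread between the control arrays alone it recovered 68%, 90%, 100% and 100%, with 8 unchanged genes called. Camera called a simulated lipogenesis shift of -1 (log2, adjusted p = 0.00101) and not one of -0.5 (0.621), with 0 of the other lists called. The simulated genes were independent, while lipogenesis genes had an estimated correlation of 0.708 in the data. The simulation therefore does not show how often camera calls lists whose genes move together. The fit of the compounds' second against first arrays recovered 2%, 52%, 86% and 100% of the same fold sizes, with 6 unchanged genes called.

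Alternatives were quantile normalization, centring of each array, no dim probe sets (the dimmest by mean left out), a trended and robust variance, only the arrays of the groups compared, an additive term for the replicate number, the other deposited table, other thresholds, the authors' own p-values, SQ as 0 units in the trend, and leaving out each array in turn. After the second arrays of the compounds were seen to stand apart, fits with those arrays as a block, with the first arrays of the compounds only, and with the control arrays averaged were added, together with a comparison of the second with the first arrays (compound as a block) and the list tests between neighbouring derivatives. Correlations between comparisons that share the control arrays were set beside 100 simulations of unchanged groups. Predicted loci and probe sets with several symbols were left out of the naming but not of the tests of genes. The precision is limited by the number of arrays and by the spread between the arrays of a compound, as the simulated data show. In the weighing of causes, a split test that ignored the compounds, a median over spikes of both kinds and a comparison of levels between probe sets were replaced or dropped after their values were seen, since they could not answer their question. A wider bound for the hybridization spikes, the median absolute difference of the genes called, was also tried after their values were seen and was not kept, since those genes were selected for their difference.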

Results

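The data are log2 signals of 22206 probe sets in 12 arrays of 3T3-L1 cells: control, SQ, mono-SQ, di-SQ, tri-SQ and tetra-SQ, with 2 arrays each. Squalene is the precursor of sterols, and the derivatives carry ethylene glycol units. Per the labels, the compounds were present at 5 µM over 14 days. The controls are labelled as without treatment and without induction, while the protocol describes a hormone mix with or without compound. The labels do not say that the 2 arrays of a group come from separate cultures, so they may be technical replicates. The upper quartile of the signals lay between 8.95 and 9.16 (log2) in all 12 arrays. Levels are log2 means ± SD over the 2 arrays of a group unless stated, and differences are log2 ± SE from limma.

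Fat cell transcripts gave signals above the negative control probe sets in the control arrays. Adipoq, which encodes the hormone adiponectin, stood at 17.43 ± 0.03, the fatty acid carrier Fabp4 at 18.30 ± 0.08, the lipid droplet coat protein Plin1 at 15.28 ± 0.01, and the insulin-responsive glucose transporter Slc2a4 at 12.11 ± 0.04 (SD, n = 2 each). Lipoprotein lipase (Lpl, 18.12 ± 0.02), the desaturase Scd1 (19.64 ± 0.00) and the nuclear receptor Pparg (15.53 ± 0.06) also lay above them. Leptin (Lep, 4.78 ± 0.01) lay below the negative control medians (6.263 and 6.269, from the other deposited table). Dlk1, a surface protein of preadipocytes, was at 16.59 ± 0.03. Beyond the negative controls, levels of different probe sets are not compared, and no array of undifferentiated cells was present to set them against.

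The second array of each compound stood apart from its first array and from both controls. In the second arrays, Plin1 was at 10.35 ± 0.24 against 15.03 ± 0.22 in the first (SD, n = 5 each), Slc2a4 at 6.99 ± 0.29 against 11.97 ± 0.20, and the immediate early gene Egr1 at 15.84 ± 0.13 against 10.04 ± 0.19. The first principal component, with 53.8% of the variance, separated the 5 second arrays from the other 7. Across genes, which are not independent replicates, the control arrays correlated at 0.9974, the 2 arrays of a compound at 0.9677 to 0.979, first compound arrays with controls at 0.9888 to 0.9927, and second compound arrays with controls at 0.9768 to 0.9791. Probe sets that differed by over 1 log2 unit between the 2 arrays of a group numbered 50 in control and 2263 to 3669 in the compounds. Every comparison with control below therefore averages 2 unlike arrays, and the medians of the main lists are also given within each replicate number. Of the 42 results named below as nearest to the threshold, 22 lay in all groups compared under the lowest negative control median of any array (6.095), among them Mas1, Lipo4, Capn11, Tlr6, Pik3cd, Cdh1 and Ak8, and may not be signal. Of 104 results named from lists, 3 did (Psmb8 in SQ, Rtp4 in di- and tetra-SQ). For others only the lower group lay under it, among them Xaf1 (5.06 in control), Cdc20 (5.69), Ccl8 (5.52) and Pnpla3 (5.42 in SQ). The sizes of their differences are uncertain. The median control level of the interferon-stimulated list (6.34) was near the negative control medians.

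**Figure D1:**
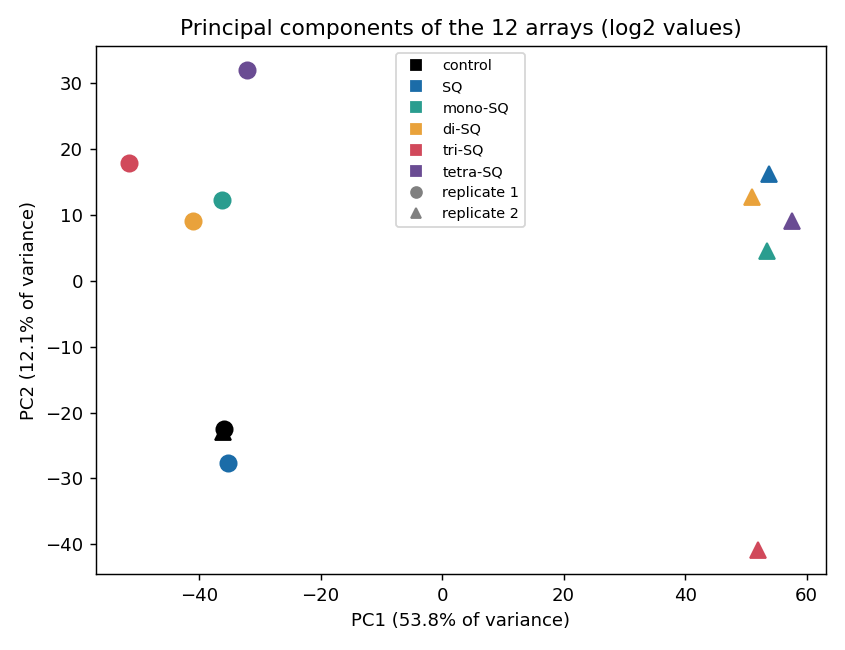
Principal components of the 12 arrays, computed on log2 signals (axes: component scores, with the share of variance). Circles are replicate 1, triangles replicate 2, colours the groups, and the second arrays of the 5 compounds lie on the right of the first component, which holds 53.8% of the variance.

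Squalene against control asks what the parent compound does to these cells. Fat synthesis genes were lower as a group: 19 of 21 lipogenesis genes were below control, with a median difference of -1.01 (camera, adjusted p = 0.0029). Among them were Dgat1 (-2.13 ± 1.94, SE) and Dgat2 (-2.0 ± 2.03), which make triglyceride, and the lipid droplet enzyme Pnpla3 (-2.16 ± 1.25). Mature adipocyte genes had a median of -1.38 (25 of 26 lower, adjusted p = 0.00115), with Slc2a4 at -2.78 ± 2.60, Plin1 at -2.5 ± 2.44 and glycerol-3-phosphate dehydrogenase (Gpd1) at -2.25 ± 2.21. Of 25 cholesterol synthesis genes, 23 were lower (median -0.71, adjusted p = 0.00115), among them the late enzymes Dhcr7 (-1.46 ± 1.35) and Cyp51 (-1.24 ± 1.13) and the sterol sensor partner Insig1 (-1.28 ± 1.13). With an estimated correlation, the adjusted p of each of these lists was 0.94.

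Higher in SQ were ribosomal protein, interferon-stimulated and cell cycle genes. All 20 ribosomal protein genes were above control (median 0.70, adjusted p = 3.77e-11), including Rpl10a (1.19 ± 0.50), Rpl7 (1.08 ± 0.29) and Rpl18 (0.97 ± 0.51). Of 32 interferon-stimulated genes 29 were higher (median 0.50, adjusted p = 0.00115), with Xaf1 at 2.06 ± 0.89, the immunoproteasome subunit Psmb8 at 1.42 ± 0.49 and Oasl2 at 1.22 ± 1.07. Of 29 cell cycle genes 26 were higher (median 0.59, adjusted p = 0.0033), with the replication clamp Pcna at 1.24 ± 0.60, Cdc20 at 1.15 ± 0.70 and Mcm5 at 1.05 ± 0.66. The adjusted p with an estimated correlation was 0.94 for all 3. Inflammatory mediators did not pass (median 0.24, adjusted p = 0.129), and the chemokines Ccl7 (1.8 ± 0.98) and Ccl2 (1.68 ± 1.06) and the prostaglandin synthase Ptgs2 (1.14 ± 1.59) did not pass either. In the first SQ array the lipogenesis median was -0.17 and in the second -1.78 relative to the control of the same number. For mature adipocyte genes these values were -0.13 and -2.65, and for cholesterol synthesis -0.24 and -1.29. They were, for interferon-stimulated genes, -0.04 and 1.18, for the cell cycle -0.13 and 1.28, for ribosomal proteins 0.27 and 1.15, and for inflammatory mediators 0.17 and 0.33. No single gene passed the limma test: 0 of 22206 probe sets at an adjusted p under 0.05, with 1117 at an unadjusted p under 0.05 (551 higher, 566 lower) and a smallest adjusted p of 0.92. The 1117 are 5.03% of all. The spread in this fit holds the shift between first and second arrays, which the compounds share. The share expected without any change therefore need not match the threshold, and 5.03% does not show that nothing changed. The share under 0.05 was 5.57% to 8.49% for the derivatives against control and 1.85% to 5.26% for the compounds against each other. Closest to the threshold were Mas1 (-1.6 ± 0.25), Lipo4 (-1.41 ± 0.24) and Capn11 (-1.2 ± 0.25). Adjusted over the list alone, Rpl7 and Rps18 passed among ribosomal proteins (adjusted p = 0.0492 each). Here and below, this adjustment leaves out the number of lists and comparisons searched. Over all genes, limma gave both an adjusted p of 0.921.

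**Figure D2:**
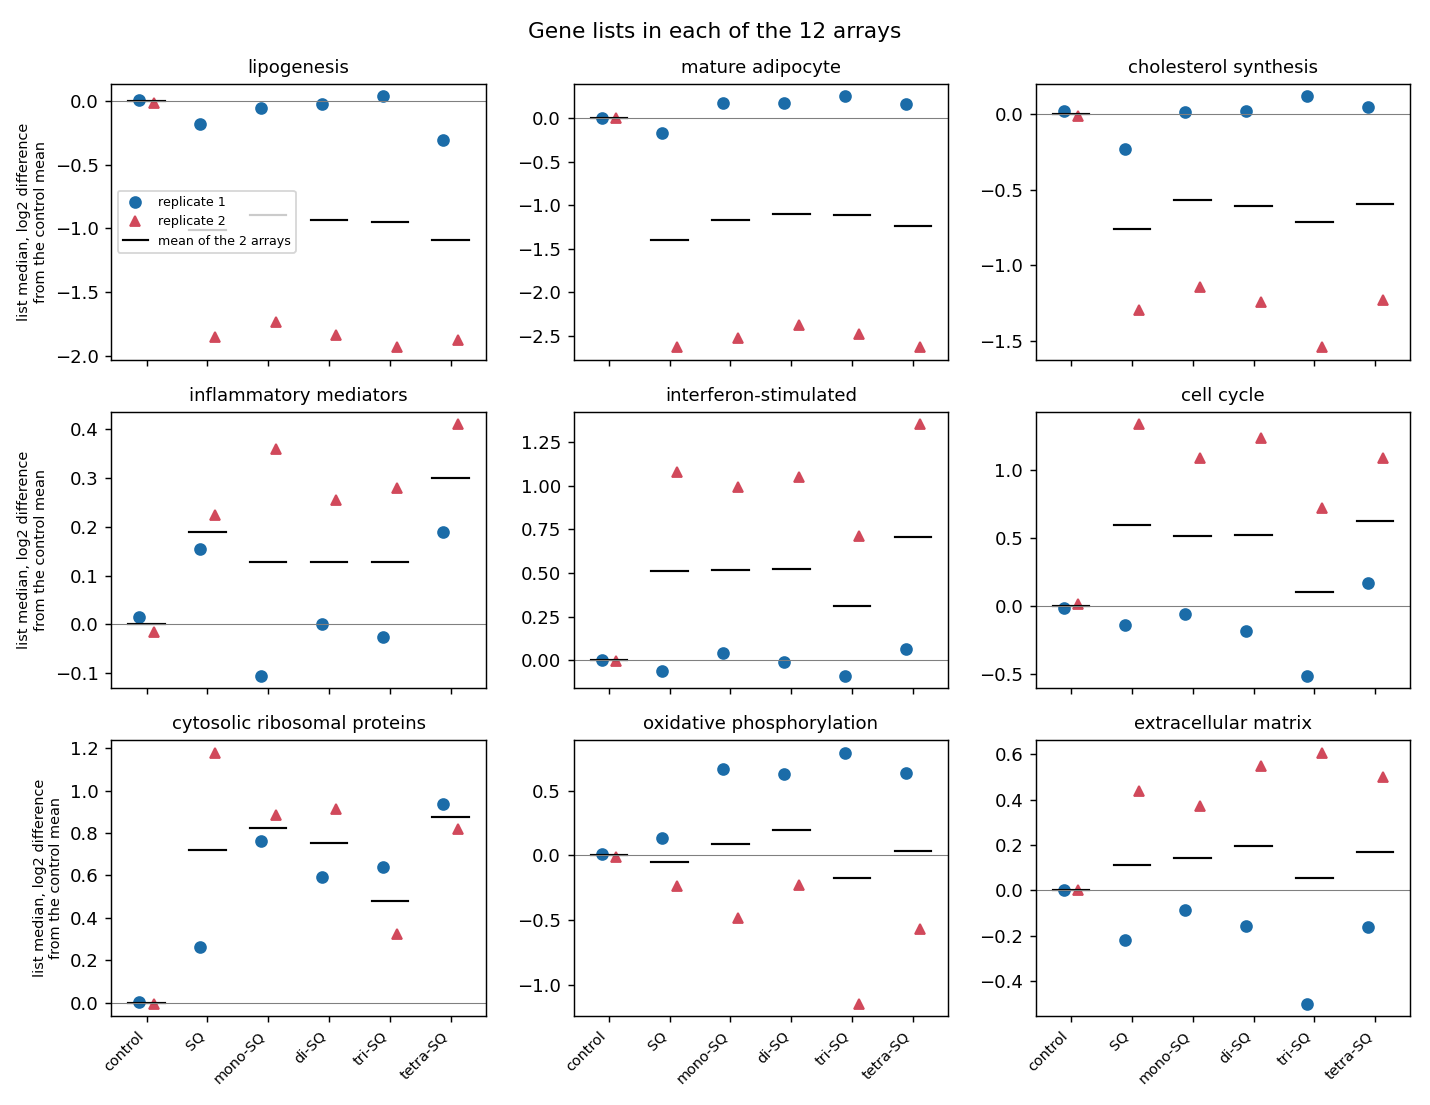
Medians of 9 gene lists in each of the 12 arrays (vertical axis: log2 difference from the mean of the control arrays). Circles are replicate 1, triangles replicate 2, black bars their mean; ribosomal protein genes lie above both controls in all 10 compound arrays (0.26 to 1.18), while lipogenesis genes are 0.04 to -0.31 in first and -1.74 to -1.94 in second arrays.

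Mono-SQ, with a single glycol unit if the prefix counts them, was compared with control in the same way. Lipogenesis genes were lower (19 of 21, median -0.83, adjusted p = 0.0149), with Dgat2 at -2.08 ± 2.03, Dgat1 at -1.86 ± 1.94 and Pnpla3 at -1.7 ± 1.25. Mature adipocyte genes (23 of 26 lower, median -1.12, adjusted p = 0.0206) included Slc2a4 (-2.81 ± 2.60), Plin1 (-2.59 ± 2.44) and Gpd1 (-2.3 ± 2.21), and cholesterol synthesis genes (21 of 25 lower, median -0.54, adjusted p = 0.0273) included Mvd (-1.16 ± 0.97), Insig1 (-1.11 ± 1.13) and Dhcr7 (-1.11 ± 1.35). All 20 ribosomal protein genes were higher (median 0.81, adjusted p = 6.4e-15), as were 29 of 32 interferon-stimulated genes (median 0.55, adjusted p = 0.00159) and 25 of 29 cell cycle genes (median 0.49, adjusted p = 0.0431). For these 6 lists the adjusted p was 0.94 with an estimated correlation. Examples were Rpl10a (1.56 ± 0.50), Rpl5 (1.13 ± 0.41) and Rpl11 (1.1 ± 0.36), Xaf1 (1.49 ± 0.89), the viral tether Bst2 (1.28 ± 0.90) and Mx2 (1.23 ± 1.08), and Cdc20 (1.3 ± 0.70), Pcna (1.29 ± 0.60) and the mitotic kinase Cdk1 (0.93 ± 0.85). The inflammatory list did not pass (median 0.03, adjusted p = 0.301), with Ccl2 at 1.95 ± 1.06, Ccl7 at 1.72 ± 0.98 and Ccl8 at 1.4 ± 0.70. Within replicates 1 and 2 the medians were -0.11 and -1.76 for lipogenesis, 0.17 and -2.58 for mature adipocyte, -0.01 and -1.12 for cholesterol synthesis, 0.01 and 1.01 for interferon-stimulated, -0.03 and 1.06 for cell cycle, 0.76 and 0.87 for ribosomal protein, and -0.10 and 0.40 for inflammatory genes. The limma test called 0 genes (1310 at an unadjusted p under 0.05, smallest adjusted p = 0.837). Nearest were Lipo4 (-1.4 ± 0.24), Mas1 (-1.35 ± 0.25) and the Toll-like receptor Tlr6 (-1.97 ± 0.37). Adjusted over the list alone, 10 ribosomal protein genes passed.

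In di-SQ cells, lipogenesis genes were again below control (19 of 21, median -0.80, adjusted p = 0.0248), with Dgat2 at -1.8 ± 2.03, Dgat1 at -1.61 ± 1.94 and the acyl-CoA synthetase Acsl1 at -1.44 ± 1.44. Mature adipocyte genes (25 of 26 lower, median -1.06, adjusted p = 0.0206) included Slc2a4 (-2.38 ± 2.60), Plin1 (-2.3 ± 2.44) and Gpd1 (-2.12 ± 2.21). Cholesterol synthesis genes (21 of 25 lower, median -0.56, adjusted p = 0.0321) included Dhcr7 (-1.52 ± 1.35), Mvd (-1.06 ± 0.97) and Cyp51 (-0.96 ± 1.13). Ribosomal protein genes were all 20 higher (median 0.69, adjusted p = 6.4e-15), with Rpl10a at 1.53 ± 0.50, Rpl11 at 1.17 ± 0.36 and Rpl18 at 1.16 ± 0.51. Interferon-stimulated genes (29 of 32 higher, median 0.52, adjusted p = 0.00212) included Rtp4 (1.55 ± 0.80), Xaf1 (1.5 ± 0.89) and Bst2 (1.19 ± 0.90), and cell cycle genes (25 of 29 higher, median 0.45, adjusted p = 0.0321) Pcna (1.45 ± 0.60), Bub1 (0.79 ± 0.69) and Cdk1 (0.79 ± 0.85). The adjusted p of all 6 was 0.94 with an estimated correlation. Inflammatory mediators did not pass (median 0.20, adjusted p = 0.189), with Ccl2 at 1.63 ± 1.06, Ccl7 at 1.62 ± 0.98 and Ptgs2 at 1.15 ± 1.59. Medians within replicates 1 and 2 were -0.03 and -1.76 for lipogenesis, 0.18 and -2.40 for mature adipocyte, 0.03 and -1.22 for cholesterol synthesis, -0.09 and 1.01 for interferon-stimulated, -0.24 and 1.22 for cell cycle, 0.63 and 0.91 for ribosomal protein, and 0.02 and 0.25 for inflammatory genes. Of all probe sets 0 passed in limma, 1237 had an unadjusted p under 0.05, and the smallest adjusted p was 0.886. Nearest were Mcts2 (1.08 ± 0.19), Lipo4 (-1.35 ± 0.24) and Arhgef5 (-1.03 ± 0.18). Adjusted over the list alone, Rpl7 and Rps18 passed (adjusted p = 0.0479 each).

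In tri-SQ, fat and sterol synthesis genes were below control and ribosomal protein genes above it. Lipogenesis (19 of 21 lower, median -0.92, adjusted p = 0.0206) and cholesterol synthesis genes (24 of 25 lower, median -0.62, adjusted p = 0.0029) were lower. Examples were Dgat1 (-1.92 ± 1.94), Pnpla3 (-1.79 ± 1.25) and Dgat2 (-1.77 ± 2.03), and squalene epoxidase (Sqle, -1.27 ± 1.13), Cyp51 (-1.24 ± 1.13) and Fdps (-1.01 ± 0.98). Fatty acid oxidation (19 of 21 lower, median -0.59, adjusted p = 0.0242) and glycolysis genes (15 of 16 lower, median -0.32, adjusted p = 0.0245) also passed. Among them were Ucp3 (-1.3 ± 1.16) and Cpt2 (-1.04 ± 1.26), and hexokinase 2 (Hk2, -1.28 ± 1.13), Pfkfb3 (-1.03 ± 1.37) and Pfkp (-0.76 ± 0.46). Ribosomal protein genes were higher (18 of 20, median 0.51, adjusted p = 0.00035), with Rpl10a at 0.94 ± 0.50, Rpl11 at 0.72 ± 0.36 and Rpl27 at 0.69 ± 0.38. For each of these 5 lists the adjusted p was 0.94 with an estimated correlation. Mature adipocyte genes (median -1.06, adjusted p = 0.0526; Plin1 -2.66 ± 2.44, the adipokine Cfd -2.51 ± 2.65, Slc2a4 -2.39 ± 2.60) did not pass. Nor did interferon-stimulated genes (0.28, 0.227), cell cycle genes (0.11, 0.886) or inflammatory mediators (0.19, 0.435; Ccl7 1.54 ± 0.98, Ccl2 1.45 ± 1.06, Ptgs2 1.08 ± 1.59). Medians within replicates 1 and 2 were 0.04 and -1.86 for lipogenesis, 0.14 and -1.48 for cholesterol synthesis, 0.02 and -1.18 for fatty acid oxidation, -0.03 and -0.77 for glycolysis, and 0.64 and 0.32 for ribosomal protein genes. For the 4 lists that did not pass they were 0.31 and -2.525 (mature adipocyte), -0.035 and 0.63 (interferon-stimulated), -0.49 and 0.72 (cell cycle) and -0.02 and 0.31 (inflammatory). Limma called 0 genes (1483 at an unadjusted p under 0.05, 799 higher and 684 lower; smallest adjusted p = 0.655). Nearest were the lipid phosphatase Plpp2 (-1.35 ± 0.22), the palmitoyltransferase Zdhhc18 (-1.31 ± 0.22) and Lipo4 (-1.35 ± 0.24). Adjusted over the list alone, the macrophage marker Mrc1 (-1.19 ± 0.30, adjusted p = 0.0455) and the bone matrix gene Ibsp (1.38 ± 0.26, adjusted p = 0.00509) passed. Over all genes, limma gave both an adjusted p of 0.669.

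Tetra-SQ cells were compared with control last. Lipogenesis (19 of 21 lower, median -1.10, adjusted p = 0.0194) and mature adipocyte genes (25 of 26 lower, median -1.18, adjusted p = 0.0273) were lower. Among them were Dgat2 (-2.37 ± 2.03), Dgat1 (-1.96 ± 1.94) and Acsl1 (-1.86 ± 1.44), and Plin1 (-2.9 ± 2.44), Slc2a4 (-2.75 ± 2.60) and Gpd1 (-2.69 ± 2.21). All 20 ribosomal protein genes (median 0.89, adjusted p = 5.71e-14), 28 of 32 interferon-stimulated genes (median 0.66, adjusted p = 0.00105) and 25 of 29 cell cycle genes (median 0.67, adjusted p = 0.00307) were higher. The adjusted p of these 5 lists was 0.94 with an estimated correlation. Examples were Rpl10a (chromosome 17, 28328471 to 28331033, GRCm38; 1.81 ± 0.50), Rpl18 (1.26 ± 0.51) and Rpl5 (1.2 ± 0.41), Xaf1 (1.99 ± 0.89), Rtp4 (1.51 ± 0.80) and Bst2 (1.38 ± 0.90), and Pcna (1.61 ± 0.60), Ccnb2 (1.35 ± 0.89) and thymidylate synthase (Tyms, 1.05 ± 0.48). Cholesterol synthesis (median -0.61, adjusted p = 0.0843; Dhcr7 -1.48 ± 1.35, Insig1 -1.29 ± 1.13, Mvd -1.28 ± 0.97) and inflammatory mediators (0.26, 0.121; Ccl2 1.9 ± 1.06, Ccl7 1.69 ± 0.98, Ptgs2 1.63 ± 1.59) did not pass. Within replicates 1 and 2, medians were -0.30 and -1.87 for lipogenesis, 0.18 and -2.66 for mature adipocyte, 0.07 and 1.31 for interferon-stimulated, 0.15 and 1.10 for cell cycle, 0.98 and 0.80 for ribosomal protein, 0.03 and -1.28 for cholesterol synthesis, and 0.15 and 0.28 for inflammatory genes. In limma 0 genes passed (smallest adjusted p = 0.573), with 1886 at an unadjusted p under 0.05 (844 higher, 1042 lower). Nearest to the threshold were Pik3cd (-1.33 ± 0.24), Phf7 (1.25 ± 0.23) and Mcts2 (0.94 ± 0.19). Adjusted over the list alone, 10 ribosomal protein genes and the cartilage link protein Hapln1 (-1.34 ± 0.31, adjusted p = 0.0233) passed. Over all genes, limma gave each an adjusted p of 0.58.

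Lipogenesis and ribosomal protein lists passed in all 5 comparisons with control, and mature adipocyte, cholesterol synthesis, interferon-stimulated and cell cycle lists in 4 each. In total 28 of 145 list tests passed (13 higher, 15 lower), 0 with an estimated correlation (smallest adjusted p = 0.94) and 0 with fry (0.945). With the compounds' second arrays as a block, an alternative chosen after the data were seen, lipogenesis passed in 0 comparisons (median -0.28 to 0.007) and mature adipocyte genes in 1 (-0.08 to 0.20). This block holds compound arrays only, so it takes up the whole shift their second arrays share, a response in them included. The compounds are then set against control near the level of their first arrays. In that fit, cholesterol synthesis passed in 0 (-0.10 to 0.10), interferon-stimulated genes in 1 (-0.21 to 0.14) and cell cycle genes in 1 (-0.53 to 0.07), while ribosomal protein genes passed in all 5 (0.41 to 0.79). Except for ribosomal protein genes the direction of these calls had turned: mature adipocyte genes passed as higher in di-SQ (0.201, against -1.06 without the block), and interferon-stimulated (-0.208) and cell cycle genes (-0.525) as lower in tri-SQ, where they had been 0.28 and 0.11 without a call. Lists without a call in the first fit passed there too: oxidative phosphorylation in all 5 (0.46 to 0.823), oxidative stress defence in 3 (0.141 to 0.318), extracellular matrix in 2 (-0.338 to -0.16) and matrix remodelling enzymes in 1 (-0.432 to -0.09). Of the 145 tests in that fit 19 passed, and 0 with an estimated correlation (smallest adjusted p = 0.998). Without the second array of the compound, the lipogenesis median was -0.31 to 0.04 in the 5 comparisons and passed in 0 of them. Inflammatory mediators passed in 0 of the 5 comparisons with control, with medians of 0.03 to 0.26. Their median control level (5.04) lay under the lowest negative control median (6.095), so many members may not be signal. Genes called in all 5 numbered 0 in limma; at an unadjusted p under 0.05, 115 genes went the same way in all 5 (38 higher, 77 lower). The comparisons share the controls and the compounds share the shift of the second arrays, so some of this is expected without a response, and the number for unchanged groups was not computed. The authors' own table also holds 0 genes at a false discovery rate under 0.05 in each comparison.

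Across genes, which are not independent replicates, log2 differences of the compounds correlated at 0.67 to 0.83 (median 0.771), with a median of 0.667 with the second arrays as a block and 0.52 with first arrays only. The 0.771 stands against a median of 0.50 for simulated unchanged groups sharing these controls at the spread of all groups and 0.11 at the controls' own spread. The covariance was 0.128 to 0.183 (median 0.154), against 0.117 and 0.015 simulated. The simulation treats arrays as independent, while the deviations of the compounds' arrays from their group means correlated at 0.48 to 0.719 between compounds, so the simulated values are no measure of a shared response. Within replicate 1 the correlations were 0.311 to 0.644, within replicate 2 0.722 to 0.87, and between replicate 1 of a compound and replicate 2 of another, which use different control arrays, 0.026 to 0.331. Unchanged groups were simulated for the fit with all 12 arrays alone, so the other correlations do not give the size of a shared part.

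The other 20 lists passed in 0 of the 5 comparisons with control. Ranges over the 5 compounds (log2) were -0.61 to -0.46 for lipolysis, -0.68 to -0.40 for LXR targets, -0.55 to -0.37 for insulin signalling and glucose uptake, and -0.13 to 0.03 for adipogenic transcription factors. They were 0.13 to 0.28 for preadipocyte genes, -0.33 to -0.06 for brown and beige adipocyte genes, and -0.18 to 0.21 for oxidative phosphorylation. Immune and stress lists ranged from 0.03 to 0.19 (NF-kB and Toll-like receptor pathway), -0.34 to -0.03 (complement and acute phase), -0.15 to 0.11 (oxidative stress defence) and -0.22 to -0.12 (unfolded protein and integrated stress response). Extracellular matrix genes ranged from 0.04 to 0.18, matrix remodelling enzymes from 0.15 to 0.59, TGF-beta and myofibroblast genes from -0.04 to 0.23, and glucocorticoid targets from 0.03 to 0.39. Markers of macrophages (-0.12 to 0.04), osteoblasts (-0.03 to 0.15), chondrocytes (-0.18 to 0.07), muscle (-0.14 to 0.08) and endothelium (-0.10 to 0.02) lay near 0. The median control levels of these marker lists (3.93 to 5.395) and of brown and beige adipocyte genes (4.2) lay under the lowest negative control median (6.095). Many of their members may therefore not be signal, and values near 0 say little. Some of these ranges average opposite values: within replicates 1 and 2 they were 0.1 to 0.85 and -1.09 to -0.24 for oxidative phosphorylation, -0.65 to -0.05 and 1.21 to 1.36 for matrix remodelling enzymes, and -0.52 to -0.135 and 0.38 to 0.645 for extracellular matrix. The smallest adjusted p among these 20 lists was 0.121 (preadipocyte genes, lipolysis, matrix remodelling enzymes, and insulin signalling and glucose uptake).

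**Figure D3:**
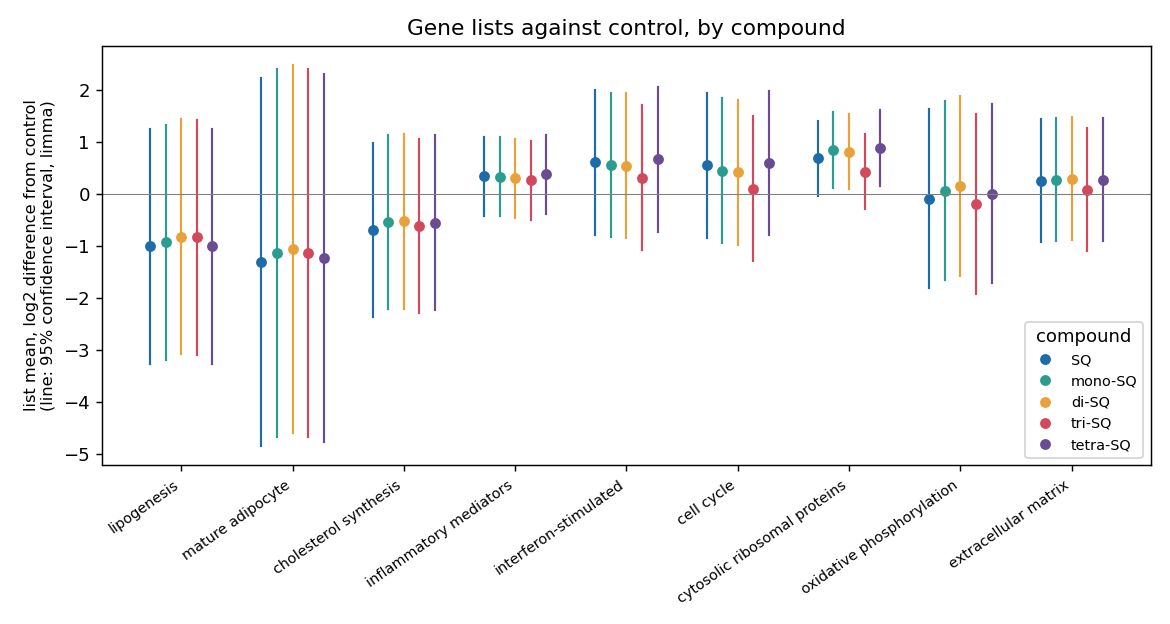
Mean log2 difference from control of 9 gene lists for each compound (points), with 95% confidence intervals from limma on the list mean per array (lines, 2 arrays per group). The intervals of the 5 compounds overlap within every list; those of ribosomal protein genes lie above 0 for mono-, di- and tetra-SQ.

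The derivatives were compared with SQ at the same dose and time to ask whether glycol units alter the response. No list passed among 116 tests (0 with camera, 0 with an estimated correlation, 0 with fry). Lipogenesis means differed from SQ by 0.08 in mono-SQ (95% interval -2.18 to 2.34), 0.19 in di-SQ (-2.07 to 2.45), 0.17 in tri-SQ (-2.09 to 2.43) and -0.001 in tetra-SQ (-2.26 to 2.26). For mature adipocyte genes the differences were 0.18 (-3.36 to 3.71), 0.25 (-3.28 to 3.79), 0.18 (-3.35 to 3.72) and 0.07 (-3.46 to 3.61), and for cholesterol synthesis 0.15 (-1.53 to 1.82), 0.16 (-1.51 to 1.84), 0.08 (-1.60 to 1.75) and 0.14 (-1.53 to 1.82). Inflammatory mediators differed by -0.004 (-0.76 to 0.75), -0.03 (-0.79 to 0.72), -0.07 (-0.83 to 0.69) and 0.05 (-0.71 to 0.81). The smallest adjusted p of a list was that of the cell cycle in tri-SQ (0.0554, median -0.44, 28 of 29 genes lower, with -0.45 in replicate 1 and -0.49 in replicate 2). Leaving out 1 compound array brought 1 to 24 of the 116 tests past the threshold, 24 without the first SQ array and 7 without the second. The intervals above ignore the replicate number, which the compounds share, and their width comes mostly from the shift between second and first arrays. Within replicates 1 and 2 the lipogenesis medians differed from SQ by 0.12 and 0.07 (mono), 0.15 and 0.15 (di), 0.19 and 0.12 (tri), and -0.13 and 0.03 (tetra). With the second arrays as a block, chosen after the data were seen, the lipogenesis intervals were -0.105 to 0.264, 0.005 to 0.373, -0.014 to 0.354 and -0.185 to 0.183 in the same order. In tri-SQ the intervals lay under 0 for cell cycle (-0.699 to -0.21) and interferon-stimulated genes (-0.471 to -0.114). So did those of matrix remodelling enzymes (-0.595 to -0.085) and preadipocyte genes (-0.445 to -0.041). All others held 0, and these intervals are not adjusted for the number of lists. In that fit 6 of the 116 tests passed, and 0 with an estimated correlation (smallest adjusted p = 0.636). The 6 were 1 each of lipogenesis, mature adipocyte, oxidative phosphorylation, interferon-stimulated, matrix remodelling and cell cycle. A p that misses the threshold does not show that the compounds act alike.

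Single genes did not separate the derivatives from SQ in limma either. In each comparison 0 passed, with 520, 520, 1106 and 819 at an unadjusted p under 0.05 for mono-, di-, tri- and tetra-SQ and smallest adjusted p of 1, 1, 0.978 and 1. Nearest were the adhesion gene Cdh1 (1.03 ± 0.26), Ribc1 (0.69 ± 0.18) and Papolg (0.72 ± 0.20) in mono-SQ, and Ak8 (-1.2 ± 0.28), Sycp1 (-1.18 ± 0.27) and Rgs8 (-1.06 ± 0.25) in di-SQ. In tri-SQ they were Zdhhc18 (-1.2 ± 0.22), Papolg (1.03 ± 0.20) and Ugt2b36 (-1.34 ± 0.26), and in tetra-SQ Zik1 (1.12 ± 0.24), Ak8 (-1.25 ± 0.28) and Papolg (0.77 ± 0.20). Adjusted over the list alone, Emcn in mono-SQ (-0.79 ± 0.20, adjusted p = 0.0366) and, in tri-SQ, the glutathione transferase Gsta4 (-0.94 ± 0.19, adjusted p = 0.0209) and Ibsp (1.1 ± 0.26, adjusted p = 0.0235) passed. Over all genes, limma gave Gsta4 and Ibsp an adjusted p of 0.959, and Emcn did not pass either.

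Neighbouring derivatives differ by 1 glycol unit in this reading of their names. Ribosomal protein genes were lower in tri-SQ than in di-SQ (20 of 20, median -0.41, adjusted p = 8.04e-05, with 0.09 in replicate 1 and -0.71 in replicate 2) and higher in tetra-SQ than in tri-SQ (20 of 20, median 0.41, adjusted p = 1.84e-05, with 0.31 and 0.56). Cell cycle genes were higher in tetra-SQ than in tri-SQ (27 of 29, median 0.57, adjusted p = 0.0025, with 0.64 and 0.31). These 3 of 87 list tests, chosen after the data were seen, had an adjusted p of 1 with an estimated correlation. The 95% intervals of the list means were -1.11 to 0.34, -0.27 to 1.18 and -0.89 to 1.89. They ignore the replicate number, whose shift the compounds share, and no fit with a block was run for these list tests. Limma called 0 genes between neighbours, with 411 (di against mono), 1000 (tri against di) and 1169 (tetra against tri) at an unadjusted p under 0.05 and smallest adjusted p of 1, 0.999 and 0.887. Nearest were the serotonin enzyme Tph2 (-0.99 ± 0.23), Lemd2 (0.78 ± 0.20) and Sycp1 (-0.97 ± 0.27) for di against mono, and Hapln3 (1.2 ± 0.24), Kcnrg (1.33 ± 0.28) and Plpp2 (-1.0 ± 0.22) for tri against di. For tetra against tri they were Gsta4 (1.04 ± 0.19), Iqcf3 (-1.78 ± 0.35) and Colec10 (-0.98 ± 0.19).

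A linear trend over mono-, di-, tri- and tetra-SQ asks whether a gene follows the number of units. Mad2l2, which acts in DNA repair, had a slope of -0.33 ± 0.07 per unit, the deacetylase Hdac11 0.25 ± 0.07 and the myeloid receptor Trem3 -0.23 ± 0.07 (SE, log2). In limma 0 genes passed (496 at an unadjusted p under 0.05, smallest adjusted p = 1). The F test over the 5 compounds called 0 genes (623 at an unadjusted p under 0.05, smallest adjusted p = 1), with Gsta4, Hapln3 and Kcnrg nearest, whose largest differences from SQ were -0.94, 1.22 and 1.47.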

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

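The values in this part belong to control probe sets that no comparison uses, and all were looked at only after the arrays had been compared. The median log2 signal of the 5222 negative control probe sets averaged 6.57 over the second arrays of the 5 compounds (6.49 to 6.66), above the 6.26 and 6.27 of the controls, and was 6.10 to 6.28 in the first arrays of the compounds.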

How the results depend on the processing

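Some of the fits below were chosen only after the result was seen: the second compound arrays as a block, first compound arrays only, averaged controls, and the comparison of second with first arrays. For gene lists, so were the other deposited table and leaving out arrays for all lists. Counts of 0 genes at an adjusted p under 0.05 in limma stayed 0 in all 14 tests under every alternative that kept this threshold. At an unadjusted p under 0.05 with at least a 2-fold change, the counts against control were 184, 233, 240, 251 and 431 for SQ, mono-, di-, tri- and tetra-SQ (184, 232, 244, 256 and 435 from the authors' p), against SQ 43, 44, 142 and 95, between neighbours 32, 116 and 175, for the trend 22 and for the F test 143. The looser threshold is the cause there. Lipogenesis lost its call with an estimated correlation and with fry, at unchanged medians of -1.01, -0.825, -0.80, -0.92 and -1.095 in the same order. With the second arrays as a block the medians were -0.153, -0.141, -0.067, 0.007 and -0.281, and with first arrays only -0.175, -0.055, -0.025, 0.04 and -0.305, so tri-SQ reversed in both. Leaving out 1 array gave -1.855 to -0.175, -1.735 to -0.055, -1.835 to -0.025, -1.935 to 0.04 and -1.88 to -0.305, and in each compound the call ended without its second array. Inflammatory mediators passed with the replicate number as a term, at 0.24 (SQ), 0.03 (mono), 0.20 (di) and 0.255 (tetra). They reversed with the second arrays as a block at -0.014 (SQ), -0.044 (mono) and -0.013 (di), and with first arrays only at -0.105 (mono) and -0.025 (tri). Over the alternatives that keep every array or set of arrays named above, their highest medians were 0.5 (SQ), 0.185 (mono), 0.297 (di), 0.185 (tri) and 0.55 (tetra). Leaving out 1 array gave 0.155 to 0.255 (SQ), -0.105 to 0.36 (mono, past the threshold without its first array), 0 to 0.255 (di), -0.025 to 0.28 (tri) and 0.19 to 0.41 (tetra). Of the 145 list tests against control, 28 passed, 0 with an estimated correlation, 0 with fry, 62 with the replicate number as a term and 23 to 36 without 1 array. The replicate numbers do not pair a compound with a control: deviations of control and compound arrays correlated at -0.001 to 0.002 across genes, and those of compounds with each other at 0.48 to 0.719. Of the 116 against SQ, 0 passed, 2 with the replicate number as a term, 6 with the second arrays as a block, 22 with first arrays only, where 1 array is set against 1 and the spread is that of the controls alone, 1 in the separately normalized table and 0 to 24 without 1 array. With an estimated correlation, 0 of the 6 and 0 of the 22 passed. The median correlation of 0.771 between comparisons became 0.667 with the second arrays as a block and 0.52 with first arrays only. The count of 4697 genes between second and first arrays was 3606 to 5101 in other fits and 1887 with at least a 2-fold change. Of 1585 alternative values of 143 named gene results, 1571 kept their direction and 14 reversed, each without the compound's second array; no gene passed an adjusted p under 0.05 in any of these fits. The 1585 values do not cover the fits with the second arrays as a block, with first arrays only or with averaged controls. Kept values moved many-fold, from -5.37 to -0.18 for Slc2a4 in SQ and from -4.12 to -0.03 for Dgat2 in mono-SQ. Their ranges without 1 array were -0.32 to 2.61 for Ptgs2 in SQ, -2.25 to 0.04 for Dhcr7 in mono-SQ, and in di-SQ -3.31 to 0.10 for Dgat1, -4.61 to 0.02 for Plin1, -2.05 to 0.13 for Cyp51 and -0.38 to 2.68 for Ptgs2. In tri-SQ they were -4.31 to 0.48 for Dgat1, -3.88 to 0.35 for Dgat2, -5.47 to 0.46 for Cfd, -4.90 to 0.13 for Slc2a4, -2.36 to 0.34 for Fdps, -0.37 to 2.54 for Ptgs2, -2.71 to 0.12 for Ucp3 and -2.51 to 0.42 for Cpt2. Fits that leave out an array assume that the lone array varies like the other groups. Except where stated, the cause was not tested. The negative control medians were 6.095 to 6.656, and 22 of the 42 results named as nearest to the threshold lay under 6.095 in all groups compared, so they may not be signal.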

Other observations

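All tests in this part were chosen only after the result was seen. The second arrays of the 5 compounds held far less of the fat cell transcripts than the first arrays. With compound as a block, limma called 4697 genes between them (2485 higher and 2212 lower in second arrays, n = 5 and 5). The genes named here were chosen after their values were seen. The p values of this comparison treat the compounds as independent repeats. The labels do not say whether the second arrays came from separate runs. These p values and counts of compounds therefore do not measure variation between runs. The growth hormone releasing hormone gene Ghrh fell by 8.23 (log2), autotaxin (Enpp2) by 6.72 and the imprinted gene Peg10 by 6.26. In second arrays Ghrh was at 6.32, under their negative control medians (6.485 to 6.656), so the size of its fall is uncertain. The mature adipocyte list was lower (-2.69, adjusted p = 1.27e-27; 0.0716 with an estimated correlation), with Cfd (-5.02), Slc2a4 (-4.98), Plin1 (-4.68), Dgat2 (-3.87), the transcription factors Cebpa (-3.12) and Pparg (-2.75), Adipoq (-3.03) and Lpl (-1.43). Lep (-0.47, adjusted p = 0.192) did not pass. Adipogenic transcription factors as a list had a median of -0.224, with 3 of 17 genes called higher and 6 lower. Camera gave that list an adjusted p of 0.0356, lost at 0.321 with an estimated correlation. The sterol enzyme Sqle fell by 2.15, while Srebf2 (-0.40, adjusted p = 0.0748) did not pass. Oxidative phosphorylation genes had a median of -1.16 (adjusted p = 5.42e-15; 0.2 with an estimated correlation).

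Some immediate early genes, which respond within minutes to serum or stress, rose in the second arrays, and no list of such genes was tested: Egr1 by 5.80, Egr2 by 4.73, Zfp36 by 4.50, Ier2 by 4.29, Junb by 4.04, Nr4a1 by 2.87 and Jun by 2.62 (log2), while Atf3 did not pass (-0.50, adjusted p = 0.0508). Fos (1.79) was at 6.41 in second and 4.61 in first arrays. Both lie under the negative control medians (6.485 to 6.656 and 6.095 to 6.28), so it may not be signal. Zfp36 (5.83) and Nr4a1 (6.17) lay under or near these medians in first arrays, so the sizes of their rises are uncertain. Also higher were Mmp9 by 4.11, Ogn by 3.91, Mmp3 by 3.39, Ptgs2 by 3.01 and the preadipocyte gene Dlk1 by 1.82. In first arrays Mmp9 (5.21) and Ptgs2 (6) lay under the negative control medians, so the sizes of these 2 rises are uncertain. Of 29 lists 21 passed (8 higher, 13 lower), and 2 did with an estimated correlation, lipogenesis (-1.86, adjusted p = 0.0344) and interferon-stimulated genes (0.95, adjusted p = 0.0204). Cytosolic ribosomal protein genes did not pass (0.10, adjusted p = 0.148). The compounds were also pooled as a single group of 5 arrays and set against the 2 controls. The first arrays then gave 0 genes in limma, with 2830 of 22206 at an unadjusted p under 0.05 and a smallest adjusted p of 0.197. The second arrays gave 4429. The 0 does not show that the first arrays equal the controls.

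What sets the second arrays apart stays open, and the cells or the measurement may be the cause. The count of genes was at least 4682 after other normalizations. All of them used deposited signals that were already normalized, so they cannot tell whether normalization is the cause. Negative control medians were 6.485 to 6.656 in second and 6.095 to 6.28 in first arrays. The 4 hybridization spikes were all lower in second arrays (-0.158 to -0.059, median -0.139, SD 0.131 over the first arrays). Gene lists moved further and both ways, and camera called 8 of them higher and 13 lower. Over the 5 compounds, lipogenesis moved by -2.03 to -1.67, cell cycle by 0.87 to 1.38 and extracellular matrix by 0.58 to 0.995. This argues against a loss of signal equal for all probe sets. In signals already normalized, a loss that differs between probe sets can appear as falls and rises. Weaker hybridization therefore cannot be excluded. Weaker labelling cannot be told apart from a change in the cells, since only 1 of 4 labelling spikes lay above the negative controls (0.141). Of 16 splits that keep 1 array of each compound in each part, 1 gave as many genes, the real one (4697, highest other 0), and 16 splits are too few for a share under 0.05. A candidate explanation is fewer differentiated cells in those cultures: the preadipocyte list was higher by a median of 0.288, in 5 of 5 compounds (adjusted p = 0.004, lost at 0.109 with an estimated correlation; 6 of 18 genes called higher and 1 lower), but this cannot separate fewer fat cells from less differentiated ones.

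Ribosomal protein genes lay above both controls in 10 of 10 compound arrays (0.26 to 1.18), and may reflect the compounds or the way the controls were handled. The lowest median over the 5 comparisons was 0.465 after other normalizations. Here too the signals were already normalized, so normalization as the cause cannot be judged from this value. The list lay above at least 98.71% of lists matched on level and gene length, which were themselves at 0.08 to 0.30. Matched lists hold unrelated genes, while ribosomal protein genes vary together (estimated correlation 0.751). The share therefore overstates the evidence and cannot exclude a shift of short and bright genes. The control arrays were nearly alike (SD of their difference 0.242, against 0.692 to 0.849 for the compounds), so an effect of control arrays handled apart cannot be told apart from one of the compounds, since no array separates them. An effect of the compounds stays open and untested.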
